A study of Mus musculus with 7 samples.

How the data were processed

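RNA was measured in alveolar macrophages, the resident phagocytes of the lung airspaces, sorted by flow cytometry from the lungs of mouse bone marrow chimeras. Per the labels, recipients on the C57BL/6 background were lethally irradiated and given marrow of which 90% was test marrow, either wild type or Suz12 conditional knockout (Suz12 cKO), and 10% was wild type competitor marrow that carried the other Ly5 (CD45) allele. There were 4 wild type and 3 Suz12 cKO libraries, which the design text calls biological replicates; grouping followed the genotype label of each sample. Whether cells from the competitor marrow were gated out of the sort, which Cre line was used and which Suz12 exons were deleted is not given in the sources used here. Per the labels' protocols, polyadenylated RNA was isolated with a column kit, made into TruSeq RNA libraries, and read as single-end reads of 85 bp on a NextSeq 500, with a stated yield of 14 to 20 M (1e6) reads per sample.

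The deposited values are whole-number counts of reads per gene, made by the authors with featureCounts on the mm10 mouse genome, per the submitters' processing notes, which give no version. The aligner, the gene annotation, the strand setting and the treatment of reads that match several genes or places are not given in the sources used here, so genes that overlap or that have near-identical copies, such as the haemoglobin genes, the Hspa1a and Hspa1b pair and the Ear genes, are uncertain. The table holds 27179 genes by Entrez number for 7 libraries, with the summed exon length of each gene as deposited by the authors; the deposited files of the single samples hold the same counts as the table of the series. Counts per library summed to between 48104653 and 79281431, above the stated number of reads, for a reason not given in the sources used here. Each library showed few genes at 1 to 5 counts and a peak at 6 to 32 counts, so a count may stand for less than 1 starting molecule; counting intervals and floors therefore cover counting error only. Replicates of a group were compared before use: log2 CPM (counts scaled to 1e6 per library) correlated across genes with Pearson's r between 0.916 and 0.969, and chi-square per degree of freedom was between 45.0 and 233, so no library was a copy of another.

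Symbols and positions came from the RefSeq annotation of GRCm38.p6, the assembly to which mm10 corresponds, by Entrez number: 25275 of 27179 genes matched, and unmatched genes held 0.829% of the counts. Genes were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 14436 genes with 99.98% of the counts; 9145 genes had no count in any library. Libraries were scaled with TMM factors and compared with edgeR 4.0.16 (quasi-likelihood test, R 4.3.3) with genotype as the sole term, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. Values per library are CPM after TMM scaling, and group values are mean ± SD with n = 4 wild type and n = 3 Suz12 cKO libraries, except that the summed haemoglobin level is CPM of the unscaled total. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of the quasi-likelihood F. A fold against a group with no count in any library was computed against a floor of 3 counts over that group. It is a lower bound as far as counting error goes and takes no account of PCR copies.

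Before the data were examined, 29 gene lists were fixed, from textbook knowledge of the polycomb complexes, of macrophages and of other cells a lung sort could hold, and 4 of them (Hox genes, developmental transcription factors, cell cycle, alveolar macrophage identity) were fixed as primary. 4 listed symbols (Ahsp, Hbb-bt, Rigi and Siglec5) matched no gene of the table. Each list was tested with camera in limma 3.58.1, two-sided, with the preset correlation of 0.01, with camera using an estimated correlation, and with fry, each adjusted over the 29 lists. The genes to name were fixed in the same way: Suz12; the 10 genes with the largest fold in each direction among called genes with at least 10 CPM in the higher genotype and ranges that did not overlap, without predicted or clone-derived symbols; the 3 smallest p-values in each direction; and the 4 members of each list with the smallest p, with 3 more by level for lists of other cell types. Of the genes so named, 3 are not reported here. Distances between libraries used log2 CPM with a prior count of 2 over the 500 most variable genes.

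The fit was tested on simulated counts drawn for the 14436 tested genes with the means and library sizes of these libraries and 200 genes changed. For the simulated Suz12 cKO against wild type comparison, 47% of 100 genes changed by 2-fold and 77% of 100 changed by 4-fold were called, and 8 of 132 calls (6.06%) were false. A simulated list of 30 shifted genes gave a camera p of 2.1e-22, and 4 of 100 unshifted lists fell under 0.05. Simulated genes were drawn independently, so this does not check camera on lists whose members move together. For Hox and cell cycle genes the estimated correlations were 0.33 and 0.21. Alternatives tried were RLE, upper-quartile or no composition factors, no filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, 1 surrogate variable (sva 3.50.0), removal of immunoglobulin, T cell receptor, haemoglobin, mitochondrial and sex-linked genes, the replicate number as a block, an adjusted p under 0.01, other expression splits and each library left out in turn. After the data had been seen, 4 more were added: a term for 3 libraries with over 10 CPM of haemoglobin transcripts, the 4 other libraries alone, those 3 alone, and counts divided by each library's low-count peak.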

Results

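Gene counts were obtained for alveolar macrophages from chimeric mice reconstituted with wild type or Suz12 cKO marrow, to ask how their transcriptome differs without Suz12, a core subunit of the gene-silencing polycomb repressive complex PRC2. The 4 wild type libraries held 79281431, 62424518, 59339061 and 48104653 counts. The 3 Suz12 cKO libraries held 63923829, 65257142 and 70473901. Libraries also differed in transcripts of other lung and blood cells. Haemoglobin transcripts summed to 192 and 155 CPM in Suz12 cKO replicates 1 and 2 and to 56.6 CPM in wild type replicate 2, against 2.29 to 5.17 CPM in the other 4 libraries. Sftpc, a surfactant gene of the alveolar epithelium, was at 4.53, 9.07 and 10.6 CPM in the same 3 libraries and at or under 0.0412 CPM in the others. These 3 libraries are called high in tissue RNA, a split made after the data had been seen.

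Suz12 (Entrez 52615, chromosome 11, 79993106 to 80034123 in GRCm38) was lower in each Suz12 cKO library than in each wild type library. It stood at 22.1, 23.6 and 15.1 CPM in Suz12 cKO and at 56.5, 56.3, 73.9 and 68.9 CPM in wild type. The means were 20.3 ± 4.53 against 63.9 ± 8.93 CPM (SD, n = 3 and n = 4). The log2 fold change was -1.65 (SE 0.18, edgeR adjusted p = 0.00134). A count summed over all exons includes exons that a conditional deletion can leave in place, so this level does not measure how many cells kept an intact gene. Of the 13 PRC2 subunits listed before the data were examined, Suz12 alone was called, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.147). The accessory subunits Phf1 and Mtf2 had log2 fold changes of 0.54 and -0.36 (adjusted p = 0.0552 and 0.0972).

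Of 14436 genes tested, 906 were higher and 580 lower in Suz12 cKO, and 12950 were not called. Increases were larger than decreases: 614 genes rose and 162 fell by at least 2-fold. The median log2 fold change was 1.57 among genes called higher, -0.68 among those called lower and 0.00 over all tested genes. Among the 10 largest increases, Col4a1 and Col4a2, adjoining type IV collagen genes on chromosome 8, averaged 459 ± 51.7 and 462 ± 32.9 CPM in Suz12 cKO. Wild type means were 13.8 ± 15.5 and 13.5 ± 14.3 CPM, for log2 fold changes of 5.05 (SE 1.33, adjusted p = 0.0451) and 5.09 (SE 1.06, adjusted p = 0.0182). Col6a3, a type VI collagen chain, averaged 182 ± 27.6 against 5.78 ± 5.51 CPM (adjusted p = 0.00739). Pdgfra, a platelet-derived growth factor receptor, rose by 5.03 on the log2 scale, and the TGF-beta co-receptor gene Tgfbr3 by 5.03. Marchf4, Armcx4, Cmah, Dlg5 and Hoxa10 completed the 10, with log2 fold changes between 4.75 and 5.49. The smallest p-values among increases belonged to Enpp5 (70.5 ± 6.32 against 5.74 ± 1.24 CPM), the TGF-beta co-receptor gene Eng (73.0 ± 3.32 against 21.1 ± 1.56 CPM) and the adaptor gene Nck2 (16.9 ± 0.706 against 1.70 ± 0.177 CPM), with adjusted p = 1.1e-04, 1.1e-04 and 1.3e-04.

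**Figure D1:**
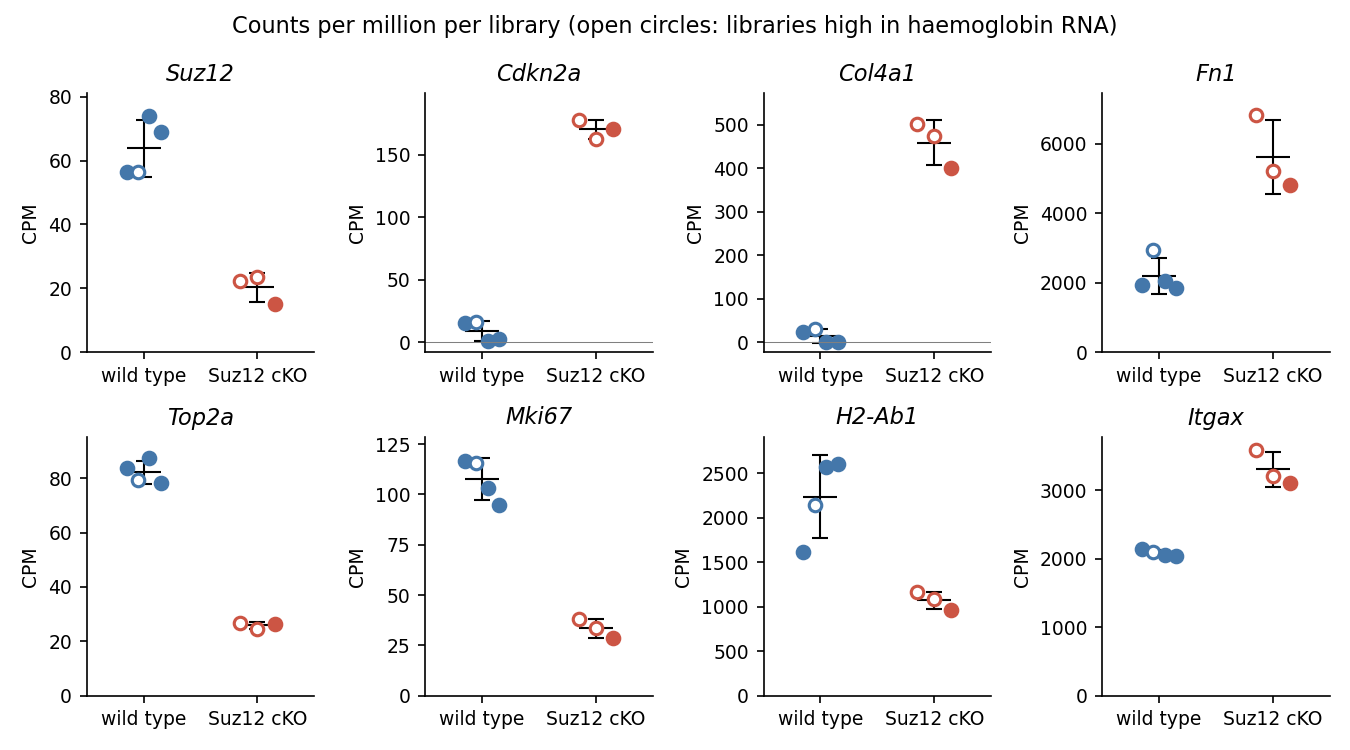
CPM of 8 genes in each library of wild type (n = 4, blue) and Suz12 cKO (n = 3, red), with 1 point per library, the mean and a bar of 1 SD; open circles are the 3 libraries high in haemoglobin RNA. Suz12, Top2a, Mki67 and H2-Ab1 were lower in each Suz12 cKO library than in each wild type library, and Cdkn2a, Col4a1, Fn1 and Itgax were higher.

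Among the 10 largest decreases, Fanci, a Fanconi anaemia repair gene, averaged 1.74 ± 0.313 against 13.8 ± 2.47 CPM (log2 fold change -2.99, SE 0.24, adjusted p = 4.6e-04). The kinesin gene Kif2c fell by 3.22 on the log2 scale, the survivin gene Birc5 by 2.37, and Prr11 by 2.39. The kinetochore and checkpoint genes Nuf2 and Bub1 had log2 fold changes of -2.24 and -2.16. The transcription factor gene Zbtb32 averaged 2.83 ± 0.610 against 17.0 ± 2.73 CPM. The receptor genes Gpr34, Gpr141 and Cd300lg had log2 fold changes of -2.92, -2.59 and -2.22. Rnase4, a secreted ribonuclease gene, averaged 66.8 ± 1.19 against 161 ± 13.6 CPM (adjusted p = 4.5e-04) and was among the 3 smallest p-values of decreases with Top2a and Ncapd2.

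Ranges did not overlap between genotypes in 1479 of the 1486 called genes and in 25.5% of all tested genes, against 5.71% by chance. The number called higher was 479, 447 and 562 without Suz12 cKO replicate 1, 2 or 3, 546 without wild type replicate 3 and 1515 without wild type replicate 2. The number called lower was 309 and 268 without Suz12 cKO replicate 1 or 2, and 299, 885 and 317 without wild type replicate 1, 2 or 3. With a term for tissue RNA 1001 genes were higher and 599 lower. Within the 4 libraries low in tissue RNA the numbers were 616 and 367, and within the 3 high ones 746 and 328, fits in which a lone library of 1 genotype is assumed to vary like the others.

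Direction was compared by expression level because PRC2 silences genes. Of the called genes with a mean under 1 log2 CPM over the 7 libraries, 94 were higher and 2 lower (97.9% higher). Of the other called genes, 812 were higher and 578 lower (58.4%; Fisher's exact test, two-sided, p = 1.0e-18, over genes, which are not independent). The difference of 39.5 percentage points was 19.2 without Suz12 cKO replicate 2 (Fisher's exact p = 0.19) and 8.53 within the 4 libraries low in tissue RNA (Fisher's exact p = 0.21). At low counts mainly large changes can be called, and large changes were mostly increases among all calls (614 against 162 at least 2-fold). The difference may therefore come in part from which changes could be called.

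Hox genes, which pattern the body axis and are classical PRC2 targets, were higher. Of 39 listed, 24 were tested, 10 rose and 0 fell, and 21 rose and 0 fell adjusted over the list alone. The median log2 fold change was 4.23, and each of the 24 was above 0 (camera adjusted p = 1.7e-11, adjusted p with an estimated correlation = 0.204). Levels were low. Hoxa10 averaged 29.3 ± 5.13 CPM in Suz12 cKO and stood at 3.29, 0.738, 0 and 0 CPM in the wild type libraries. Hoxb7 averaged 5.17 ± 1.61 against 0.543 ± 0.358 CPM, Hoxc8 3.73 against 0.0311 CPM and Hoxa11 3.79 against 0.0910 CPM. Hoxd10, at 0.894 ± 0.458 CPM in Suz12 cKO, had no count in wild type. Against the floor of 3 counts it was at least 74.1-fold higher, a bound that covers counting error only. Of 159 developmental transcription factors outside the Hox clusters, 44 were tested, 15 rose and 0 fell, and 23 rose and 0 fell adjusted over the list alone. Their median log2 fold change was 3.67 (camera adjusted p = 4.7e-14, adjusted p with an estimated correlation = 0.121). Meis1, which encodes a cofactor of Hox proteins, averaged 10.0 ± 2.07 against 0.769 ± 0.453 CPM. The homeobox gene Lhx2 averaged 17.4 ± 3.65 against 0.817 ± 0.586 CPM and the forkhead gene Foxc1 8.87 ± 2.37 against 0.127 ± 0.130 CPM. No wild type count was found for 3 Hox genes and 7 developmental factors. Their bounds lay above the list medians, so using them could not move the medians of 4.23 and 3.67.

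Of 7 CDK inhibitor genes, Cdkn2a and Cdkn2b, neighbours on chromosome 4 that encode brakes on the cell cycle, rose and 0 fell, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00838, adjusted p with an estimated correlation = 0.307). Cdkn2a (89274473 to 89294619) averaged 170 ± 7.41 against 8.93 ± 8.11 CPM (log2 fold change 4.24, SE 0.79, adjusted p = 0.0118). It stood at 15.5 and 16.4 CPM in wild type replicates 1 and 2 and at 1.02 and 2.87 CPM in replicates 3 and 4. Cdkn2b averaged 25.7 ± 4.30 against 4.83 ± 1.70 CPM (adjusted p = 0.00191), and Cdkn1a was not called (log2 fold change 1.33, adjusted p = 0.0846). Among 13 tested imprinted genes, which are expressed mainly from 1 parental copy, Igf2r, Igf2 and Ndn rose and 0 fell, and 4 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.0032, adjusted p with an estimated correlation = 0.121). Igf2 had no wild type count and was at least 138-fold higher against the floor of 3 counts, which covers counting error only. Ndn averaged 7.65 ± 2.15 against 0.533 ± 0.393 CPM. Of 21 subunits of PRC1, the partner complex of PRC2, Bmi1, Scmh1 and Cbx7 rose by 0.95, 1.18 and 1.31 on the log2 scale and 0 fell, and 3 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.00635, adjusted p with an estimated correlation = 0.121). Of Kdm6a, Kdm6b and Uty, related demethylase genes, 0 were called by edgeR, 0 had an unadjusted p under 0.05, and 0 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.909; median -0.01, mean 0.23).

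**Figure D2:**
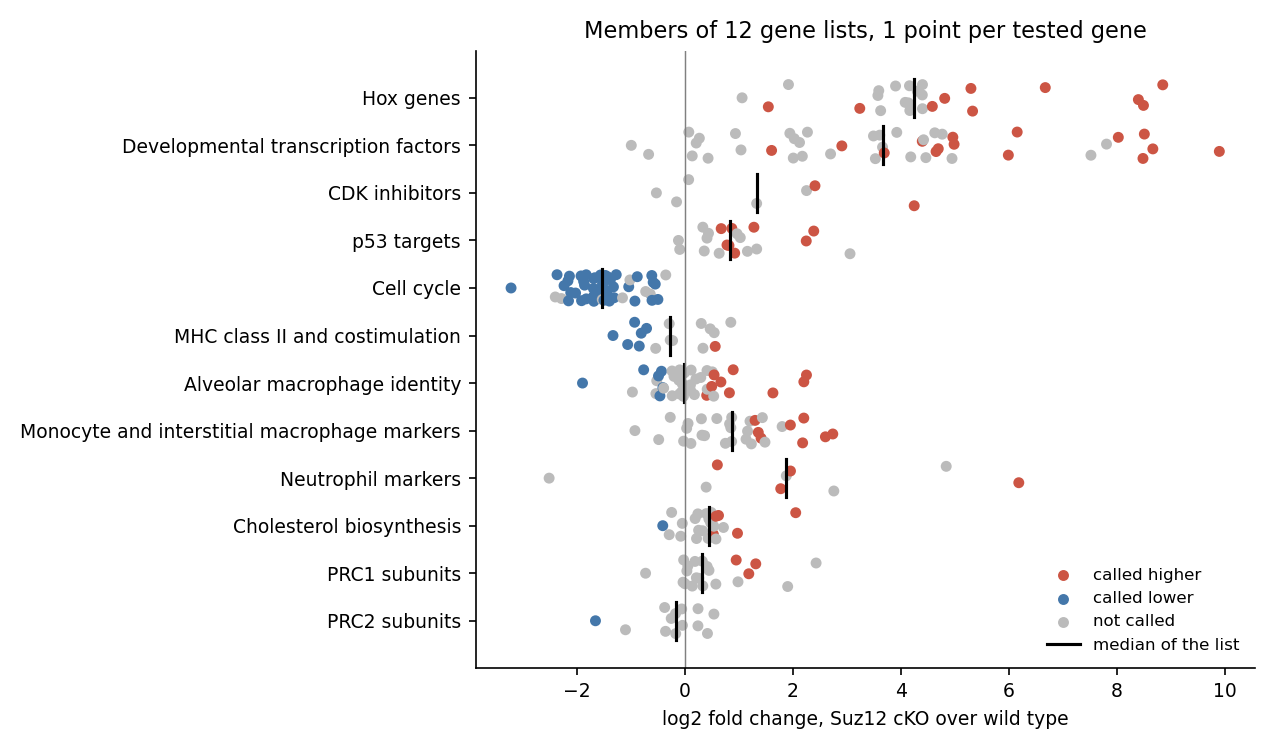
Log2 fold change (Suz12 cKO over wild type) of each tested member of 12 lists; red and blue points were called higher and lower at an adjusted p under 0.05, grey points were not called, and the black bar is the list's median. Cell cycle genes lay below 0 in all 50 members and Hox genes above 0 in all 24, while plotted folds of genes without a wild type count depend on the fit's prior count.

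Genes of the cell cycle fell together. All 50 listed genes were tested, 0 rose and 42 fell, and 0 rose and 47 fell adjusted over the list alone. The median log2 fold change was -1.53 (camera adjusted p = 1.0e-56, adjusted p with an estimated correlation = 0.0568). Top2a, the topoisomerase of dividing cells, averaged 25.9 ± 1.27 against 82.2 ± 4.31 CPM (adjusted p = 1.1e-04), and the proliferation marker Mki67 33.5 ± 4.60 against 108 ± 10.4 CPM (adjusted p = 4.5e-04). The mitotic kinesin gene Kif23 averaged 13.6 ± 1.29 against 41.0 ± 4.62 CPM and the checkpoint gene Bub1b 22.1 ± 2.77 against 62.3 ± 9.56 CPM. The condensin subunit gene Ncapd2, outside the list, fell by 1.38 on the log2 scale. Target genes of p53 moved the other way: of 20, 8 rose and 0 fell, and 15 rose and 0 fell adjusted over the list alone. Their median log2 fold change was 0.84 (camera adjusted p = 4.5e-09, adjusted p with an estimated correlation = 0.121). Zmat3 averaged 92.5 ± 8.58 against 38.1 ± 2.68 CPM, and Aen, the death receptor gene Tnfrsf10b and Ccng1 rose by 0.82, 2.25 and 0.78 on the log2 scale.

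Markers of alveolar macrophage identity went both ways. Of 40 tested, 9 rose and 6 fell, and 12 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.874). Their median log2 fold change was -0.02 and their mean 0.12, so the sign depended on the summary. Itgax, the integrin CD11c used to identify these cells, averaged 3308 ± 252 against 2083 ± 43.1 CPM (adjusted p = 9.8e-04), and the lipid-binding protein gene Fabp4 333 ± 130 against 69.9 ± 27.1 CPM (adjusted p = 0.00374). The adhesion genes Epcam (43.8 ± 14.4 against 163 ± 18.1 CPM) and Cd2 (162 ± 6.10 against 275 ± 18.3 CPM) fell. Siglecf, Pparg and Chil3, well-known markers named after their values were seen, were not called, with log2 fold changes of -0.39, -0.01 and 0.18 (adjusted p = 0.0772, 0.982 and 0.188). In the list of 16 antigen presentation genes 1 rose and 6 fell, and 1 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.00838, adjusted p with an estimated correlation = 0.531). Its mean was 6.23 to 6.53 log2 CPM in Suz12 cKO, 6.18 in wild type replicate 1 and 6.72 to 6.84 in the other wild type libraries. H2-Ab1 and H2-Aa, which encode the chains of an MHC class II molecule, averaged 1073 ± 97.6 against 2235 ± 466 CPM and 1232 ± 125 against 2346 ± 431 CPM. Their transcriptional activator Ciita averaged 48.5 against 122 CPM (adjusted p = 0.00658), and H2-DMb1 fell by 0.81 on the log2 scale.

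Lipid genes changed in part. Of 24 cholesterol biosynthesis genes 5 rose and 1 fell, and 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00134, adjusted p with an estimated correlation = 0.531). Of the 24, 7 were higher in each library high in tissue RNA than in each of the other 4, and the list mean was 5.52 log2 CPM in wild type replicate 2 and 5.51 in Suz12 cKO replicate 3. Sc5d and the regulator Srebf2 rose by 0.97 and 0.53 on the log2 scale, and Mvd fell by 0.41. Among 28 genes of surfactant and sterol handling 4 rose and 1 fell, and 7 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.456). The fatty acid transporter gene Cd36 averaged 876 ± 103 against 357 ± 145 CPM, Apoe 724 ± 377 against 272 ± 108 CPM, and Rxra fell by 0.43 on the log2 scale. Of 25 fatty acid oxidation genes, Acaa1b rose and Acads fell, and 1 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.592; median -0.04, mean 0.07). Of 26 phagocytic and scavenger receptor genes 5 rose and 1 fell, and 7 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.163). Marco averaged 15.6 ± 6.09 against 3.38 ± 2.02 CPM, and Mrc1 and Itgav rose by 0.40 and 0.60 on the log2 scale. Of 36 genes of growth factor signalling 3 rose and 1 fell, and 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0262, adjusted p with an estimated correlation = 0.575). Zeb1 averaged 18.4 ± 0.564 against 4.61 ± 2.39 CPM and the macrophage growth factor gene Csf1 19.9 ± 6.18 against 5.55 ± 4.04 CPM, Tgfbr2 rose by 0.34 on the log2 scale, and Myc fell by 0.93. In that list 13 genes were higher in each of the 3 libraries high in tissue RNA than in each of the other 4.

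Of 31 markers of monocytes and interstitial macrophages, 8 rose and 0 fell, and 8 rose and 0 fell adjusted over the list alone. The median log2 fold change was 0.87 (camera adjusted p = 2.2e-05, adjusted p with an estimated correlation = 0.511). The matrix genes Fn1 and Vcan averaged 5616 ± 1065 against 2189 ± 508 CPM and 16.8 ± 3.34 against 2.52 ± 0.562 CPM, Spp1 2860 ± 287 against 1162 ± 310 CPM, and F13a1 10.0 ± 0.876 against 1.65 ± 1.02 CPM. The mean of this list was 4.40 log2 CPM in wild type replicate 2, within the 3.74 to 4.66 of the Suz12 cKO libraries, and 2.38 to 2.85 in the other wild type libraries. Within the 3 libraries high in tissue RNA its median log2 fold change was -0.21 (camera adjusted p = 0.808), and within the 4 low ones 1.96 (camera adjusted p = 2.7e-12). Of 9 neutrophil markers 4 rose and 0 fell, and 5 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.00104, adjusted p with an estimated correlation = 0.204). The neutrophil mean was 1.11 log2 CPM in wild type replicate 2, above the 1.04 of Suz12 cKO replicate 3, and -0.32 to 0.03 in the other wild type libraries. The called genes were the calprotectin gene S100a8 (57.9 ± 16.3 against 14.9 ± 5.18 CPM), the receptor genes Cxcr2 (12.1 ± 3.89 against 3.54 ± 1.30 CPM) and Csf3r (62.3 ± 11.3 against 41.1 ± 6.27 CPM), and Retnlg (1.07 ± 0.855 against 0.0134 ± 0.0162 CPM).

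Of 35 cytokine and chemokine genes, Igf1 and Cxcl14 rose and 0 fell, and 2 rose and 0 fell adjusted over the list alone. The median log2 fold change was 1.60 (camera adjusted p = 6.2e-04, adjusted p with an estimated correlation = 0.531). Tnf was at 302, 269 and 72.9 CPM in Suz12 cKO and at 34.8, 119, 41.2 and 52.1 CPM in wild type (adjusted p = 0.0676). In this list 18 genes were higher in each library high in tissue RNA than in each of the other 4. Of 20 stress and dissociation genes, the heat shock gene Hspa1a rose (25.2 ± 20.6 against 5.87 ± 2.64 CPM) and 0 fell, and 5 rose and 0 fell adjusted over the list alone (median 0.75, camera adjusted p = 0.00451, adjusted p with an estimated correlation = 0.601), with 10 higher in each of those 3 libraries than in each of the other 4. Within the 3 libraries high in tissue RNA the medians were 0.60 for the cytokine list and -0.03 for the stress list (camera adjusted p = 0.00336 and 0.396). Within the 4 low ones they were 1.74 and 0.77. Of 8 erythroid and platelet genes 0 were called by edgeR, 1 had an unadjusted p under 0.05, and 0 rose and 0 fell adjusted over the list alone. Their median log2 fold change was 2.70 (camera adjusted p = 0.0248, adjusted p with an estimated correlation = 0.575), and their mean was -0.79 log2 CPM in Suz12 cKO replicate 3 and 1.46 in wild type replicate 2.

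**Figure D3:**
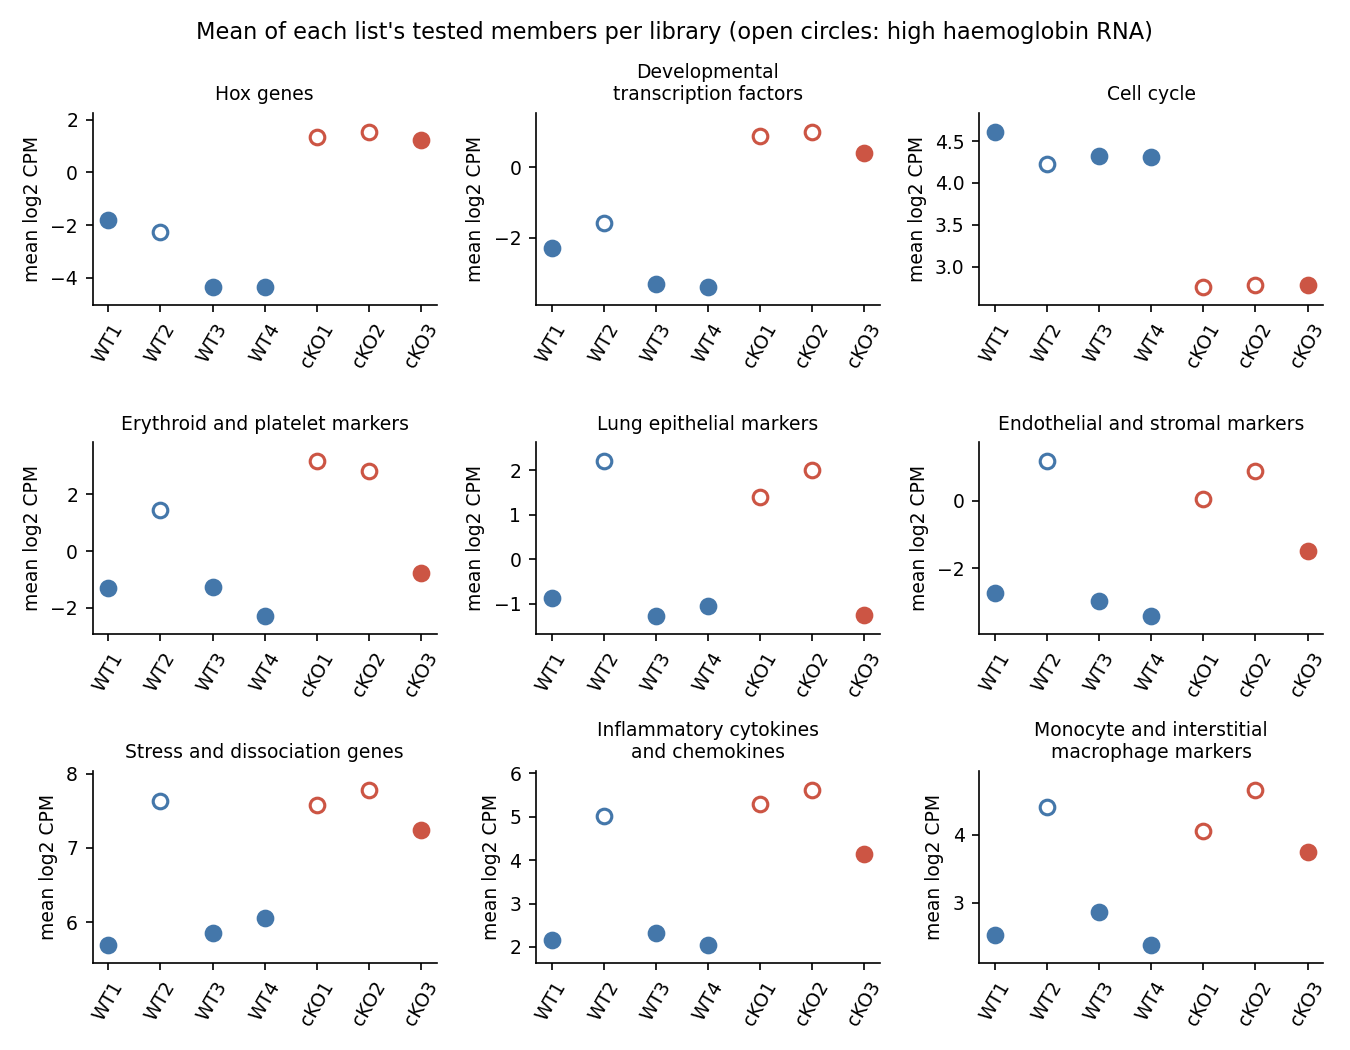
Mean log2 CPM of the tested members of 9 lists in each library (wild type WT1 to WT4, blue; Suz12 cKO cKO1 to cKO3, red; open circles, the 3 libraries high in haemoglobin RNA); the vertical axes do not start at 0. Hox and cell cycle means part by genotype, while erythroid, epithelial and stromal means part by haemoglobin RNA, with WT2 beside cKO1 and cKO2.

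Other lists were not called by camera. Among 31 interferon-stimulated genes, Mx1 alone was called (adjusted p = 0.018), and 1 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.335). Cdh1 alone rose of 19 lung epithelial markers (100 ± 12.1 against 51.0 ± 9.25 CPM; 1 rose and 0 fell adjusted over the list alone; camera adjusted p = 0.18). Pdgfra alone rose of 16 endothelial and stromal markers, and 1 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.235). Bank1 alone rose of 11 B cell markers, and 1 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.422). By edgeR 0 of 13 T and NK cell markers, 0 of 18 dendritic cell markers, 0 of 3 eosinophil and mast cell markers and 0 of 4 sex-linked genes were called (camera adjusted p = 0.18, 0.483, 0.0935 and 0.909). An unadjusted p under 0.05 was found for 0, 0, 1 and 0 of these, and 0, 0, 1 and 0 rose adjusted over the list alone. By camera 15 of the 29 lists were called. With an estimated correlation 0 were called after adjustment and 7 at an unadjusted p under 0.05. By fry, which asks whether a list's genes move on balance one way, 9 were called.

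Libraries lay farther apart between genotypes than within them, at a mean distance of 107 against 66.9 over the 500 most variable genes, a ratio of 1.61. This did not pass the test (exact permutation test over 35 splits, one-sided, p = 0.0571). The first principal component held 69.5% of the variance, with the Suz12 cKO libraries between -62.0 and -35.6, wild type replicate 2 at -9.56 and the other wild type libraries between 31.7 and 73.9.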

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

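The tests of low-count peaks, of haemoglobin in wild type replicate 1, of genes private to 1 Suz12 cKO library, of lower genes in wild type replicate 2 alone, of which genes the split of wild type replicates 1, 3 and 4 called, and each fit on the tissue-RNA split were chosen after the results that prompted them had been seen.

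Among 152 sets of 4 wild type values, 24 had 1 library far from the other 3, where chance gives about 7.6. In 21 of the 24 that library was replicate 2. Blood and lymphocyte transcripts set it apart: the haemoglobin sum at 56.56 CPM (others 2.287 to 5.174), Hbb-bs at 8.993, Hba-a2 at 20.66, Hba-a1 at 11, Car2 at 1.198, Ighm at 25.22, Il7r at 14.6 and Igkc at 26.58 CPM. Igkc had no count in the other 3. Lung tissue and mast cell transcripts included Col3a1 at 8.156, Pdgfrb at 0.2626, Sftpb at 2.035, Pdpn at 124.5 and Hdc at 2.183 CPM. Immediate-early, inflammatory and macrophage transcripts included Fos at 2334, Junb at 2553, Kdm6b at 320, Cdkn1a at 767.4, Cxcl10 at 15.64, Csf1 at 11.59, Apoe at 434.5 and Epcam at 189.6 CPM. In replicate 1, Dlg5 was at 0.7344 (others 0 to 0.1149), Hoxc8 at 0.1245 (others 0) and Kif23 at 47.85 CPM (others 37.83 to 39.34).

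Inflammatory, stress, erythroid and monocyte lists were higher in Suz12 cKO, where 2 of 3 libraries, against 1 of 4 in wild type, were high in tissue RNA. With a term for that split the erythroid median was 1.19, from 2.70, with a camera p of 0.12. The split was set by haemoglobin genes, and Hba-a1, Hba-a2 and Hbb-bs are members of this list. The fall was thus partly built in and cannot decide whether blood RNA was the source of the list's rise. The sort should remove blood cells, and 0 of the list's 8 genes reached 10 CPM in all 4 low libraries, which were picked for low haemoglobin. The inflammatory, stress and monocyte medians were 0.995, 0.505 and 0.868 (from 1.60, 0.75 and 0.87). Their camera p was 1.3e-08, 0.00433 and 1.5e-05 at the preset correlation. The estimated correlations of these lists were 0.29, 0.60 and 0.34, and camera p with these, without the term, was 0.24, 0.37 and 0.18. The term also treats the high libraries as equal, although their haemoglobin ran from 56.6 to 192 CPM. These p-values therefore cannot decide whether tissue RNA was the whole cause. Among the 3 high libraries stress and monocyte medians lay below 0 (-0.03 and -0.21). A genotype difference in these lists' medians thus rests on Suz12 cKO replicate 3, the 1 Suz12 cKO library low in tissue RNA. Single monocyte genes did differ among the high libraries. Fn1 stood at 6823 and 5214 CPM in Suz12 cKO replicates 1 and 2, against 2940 CPM in wild type replicate 2. F13a1 stood at 9.03 and 10.5 against 3.13 CPM, and Vcan and Spp1 were likewise higher in both. These genes were named for small p-values over all libraries, which favours such a gap. At least as many members lay below 0, as the list's median shows. Tissue RNA, a response to Suz12 loss and a difference in handling of the samples all stay open.

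Genes far higher in Suz12 cKO were not silent in wild type replicates 1 and 2: the 70 genes called at least 8-fold higher with 10 CPM or more stood at medians of 9.20% and 9.64% of their Suz12 cKO level there, and at 2.50% and 2.25% in replicates 3 and 4. In replicate 1, RNA from Suz12 cKO replicates 1 or 2 is argued against, since haemoglobin was at 3.23 CPM where that share would bring 14.3. Reads carried over between libraries were sought through genes private to 1 Suz12 cKO library, apart from the wild type library tested. At most 10% of these were counted in wild type replicate 1 (1 of 10 for Suz12 cKO replicate 2, 2 of 28 for replicate 3). A gene carried into both wild type replicates 1 and 2 was left out of these sets, so the share cannot decide. In wild type replicate 2 the share was 55% (11 of 20) for Suz12 cKO replicate 2 and 40% (2 of 5) for replicate 1. There carried-over reads cannot be told apart from the tissue RNA these libraries share. For Suz12 cKO replicate 3, low in tissue RNA, it was 13.3% (4 of 30), under the bound of 50% set for carried-over reads. Suz12 cKO cells or RNA in both samples would draw the 580 lower genes towards Suz12 cKO. In replicate 1 they lay at a median of -5.35% of the way (replicates 3 and 4, whose mean is the reference, at -1.09% and 1.09%). These genes were called with replicate 1 among the wild type, which favours genes high there. Suz12 itself stood at 56.5 and 56.3 CPM in replicates 1 and 2, against 73.9 and 68.9 CPM in replicates 3 and 4. The test therefore cannot decide for replicate 1. In replicate 2 the 580 genes lay at 15.7%, so such cells or RNA stay open there too, beside the shared tissue RNA. No biological explanation was tested.

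Hox and developmental transcription factors were higher in Suz12 cKO at low counts, and low counts here may be PCR copies of few molecules: of the genes counted in 1 library alone, at most 16.1% had exactly 1 count. Counts were also divided by each library's low-count peak. Then 1397 of 1486 called genes and 16 of 25 called Hox and developmental genes stayed called in the same direction. The division leaves ratios of CPM between libraries nearly unchanged, and 1403 of the 1486 were still tested. Most calls were thus bound to stay, so the test cannot decide whether PCR copies made them. With the tissue-RNA term the median log2 fold change of the 68 genes was 4.13, from 4.15. The Hox mean was 1.24 log2 CPM in Suz12 cKO replicate 3, low in tissue RNA, and -2.27 in wild type replicate 2, high in it. The developmental mean was 0.39 and -1.59 there, and -3.39 to -2.29 in the other wild type libraries. These values argue against tissue RNA as the whole cause for these lists. Loss of Suz12, which the design names, stays open as a hypothesis, untested apart from the genotype comparison.

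The 7 libraries can be split into 3 and 4 in 35 ways. For 906 genes called higher (highest other split 204) and 614 at least 2-fold higher (130), 1 split, the real one, gave as many. Its permutation p of 0.0286 is the smallest that 35 splits allow, so chance is unlikely but not excluded. The same holds for 42 lower cell cycle genes, 15 higher developmental factors and 10 higher Hox genes, with 0 in each other split. Most other splits called no gene of any kind, so those counts of 0 add little. By this count chance stays open for 580 genes called lower (highest other 639) and 162 at least 2-fold lower (492), where 2 splits gave as many. The other split set wild type replicates 1, 3 and 4, the wild type libraries low in tissue RNA, against the rest, so its lower genes are those higher in Suz12 cKO and wild type replicate 2 together. Of these 639, 257 were called higher and 0 lower in Suz12 cKO, and no remaining split gave over 11 lower genes (3 at least 2-fold lower). Within the libraries low and high in tissue RNA, 367 and 328 genes were lower.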

How the results depend on the processing

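The fits on the tissue-RNA split and on counts divided by the low-count peak were added after the data had been seen. No gene called here was called in the opposite direction under any setting of edgeR, DESeq2 or limma-voom run, and Suz12 stayed called lower in each (leave-one-out log2 fold changes -1.78 to -1.50). The labels state no pairing by replicate number. Same-numbered libraries deviated with correlations across genes of -0.04, 0.24 and 0.16, and Suz12 cKO replicates 1, 2 and 3 matched wild type replicates 2, 2 and 3 best, so 2 of 3 matched their own number. With the replicate as a block on 6 libraries 549 genes were higher and 261 lower, against 683 and 411 unblocked, and the direction difference was 32.5 points (Fisher's exact p = 0.103), with 7 low-expressed calls left. DESeq2 called 1457 higher (943 at least 2-fold). Quality weights in limma-voom gave 1920 higher, 1258 lower and 1222 at least 2-fold higher. An adjusted p under 0.01 left 355 higher and 180 lower. Within the 4 libraries low in tissue RNA 367 were lower and the direction difference was 8.53 points. Within the 3 high ones 328 were lower, and Fos (-0.63) and Il7r (-1.64), uncalled and above 0 with all libraries, were called lower, against wild type replicate 2 alone, which stood far above the other wild type libraries in both genes. There the monocyte, endothelial and stromal, and stress lists turned downwards (camera adjusted p = 0.808, 0.0105 and 0.396). With an estimated correlation the adjusted p was 0.204 for Hox genes, 0.121 for developmental factors and 0.0568 for cell cycle. Leave-one-out camera values reached at most 1.4e-10, 1.0e-12 and 3.1e-43. Over all filtered genes the distance ratio was 1.31 (exact permutation p = 0.0286, the smallest 35 splits allow). Leaving out 1 library in turn gave 447 (without Suz12 cKO replicate 2) to 1515 (without wild type replicate 2) higher and, at the same libraries, 268 to 885 lower, 343 to 1050 at least 2-fold higher and 106 to 203 at least 2-fold lower. Of the 1486 called genes, 676 to 1448 stayed called. The direction difference was 19.2 (without Suz12 cKO replicate 2) to 40.3 points (without Suz12 cKO replicate 3). The cause of these changes was not tested. Depth limits genes near the low-count peak of 6 to 32 counts.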

Other observations

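The count of neighbours without overlapping genes and the search of gene families were added after the results had been seen. Genes called higher were neighbours in the genome more often than their number gives. Outside the Hox clusters 98 adjacent pairs of tested genes were both higher, against a mean of 56.5 (43 to 70) in 10000 shuffles of the calls within expression deciles (permutation p = 1e-04, the smallest these shuffles can give). Genes overlapped in 8 of these pairs, and without overlaps there were 90 pairs against 37 to 63 in shuffles (permutation p = 1e-04). Both genes were at least 2-fold higher in 46 pairs, among them Myo1d and Tmem98 on chromosome 11, named after their values were seen. Genes called lower gave 39 pairs against 23.4 (permutation p = 0.0014), so the excess was not particular to increases. A single shuffle taken as control gave 52 pairs (permutation p = 0.749). Activation of neighbouring genes together may account for the 98 pairs, but regulation shared for other reasons gives the same result. Some pairs hold related genes, such as Ear1 and Ear10, Cyp4a12a and Cyp4a12b, and Krt79 and Krt78. Such pairs were not left out, and counts of near-identical copies are uncertain here.

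Few genes passed a strict bound for silent genes that switched on. By a bound of under 0.1 CPM in every wild type library and at least 1 CPM in every Suz12 cKO library, 9 genes were on in Suz12 cKO alone and 0 in wild type alone. They included Slc32a1, a vesicular transporter gene of inhibitory neurons, at a mean of 3.02 CPM, and the growth factor gene Bmp2 at 1.79 CPM, named after their values were seen. The split of Suz12 cKO replicates 1 and 2 with wild type replicate 2, the libraries high in tissue RNA, gave 14. By this bound the hypothesis that Suz12 loss switches on more silent genes than other splits do was not met. Wild type replicates 1 and 2, however, held medians of 9.20% and 9.64% of the Suz12 cKO level of strongly raised genes. Hoxa10, at 0 CPM in wild type replicates 3 and 4, failed the bound through replicates 1 and 2 (3.29 and 0.738 CPM). The count is therefore a low estimate of genes silent in part of the wild type libraries.

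Symbol families, 221 in all, were searched for an excess of calls with Fisher's exact test. A family was set by the letters before the first digit of the symbol and held at least 8 tested genes. Mcm genes, most of which encode the replicative helicase, had 8 of 10 lower (exact test, adjusted p = 1.2e-07), and Kif genes, the kinesins, 9 of 31 lower and 4 higher (exact test, adjusted p = 5.2e-04 for lower). No family so defined had an excess of higher genes after adjustment (smallest adjusted p = 0.449, for Dock, with 4 of 11, and Sema, with 4 of 12). This rule parts Hox genes by cluster: Hoxa had 3 of 11 higher (exact test, adjusted p = 0.783), where the whole Hox list had 10 of 24. The search therefore does not speak to Hox genes as 1 family.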
